A study of Danio rerio with 8 samples.

How the data were processed

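The series measured gene expression by RNA sequencing in cells sorted from the brains of 6-month-old (6 mpf) zebrafish that carried a reporter with green fluorescent protein (GFP) under the her4.1 promoter. Per the labels, brains were injected with interleukin-4 (IL4) peptide or with phosphate-buffered saline (PBS), and cells were taken 24 hours post injection (hpi), dissociated and sorted by flow cytometry into GFP-positive and GFP-negative fractions. The 4 groups hold 2 libraries each, 8 in all. The design text of the series describes other injections (CPP and AB42), another time (48 hours) and 3 replicates in each group. The labels of the libraries were followed instead, since their names match the columns of the deposited table. The labels do not say whether replicates are separate fish or pools, so the p-values may measure technical spread.

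The deposited table holds read counts per gene, as whole numbers with no normalization, for all 8 libraries. The authors' processing notes name featureCounts as the counter and GRCz10 (danRer10) as the genome build, and versions were not given in the sources used here. Aligner, strand setting and the handling of reads with several alignments were not stated, so values of near-identical paralogues such as the her4 genes depend on an unknown choice. The deposited table also gives each gene's length in bases, which was checked to equal its merged exon length. Of the 8 columns of counts, 0 were left without a sample. Coordinates are those of the table, from the first exon start to the last exon end. Symbols came from a table that pairs gene identifiers with names. Of 31388 genes, 25925 had a symbol and 5463 had none, and 4151 share their symbol with another gene of the table because many zebrafish paralogues carry the symbol of the human gene. Those are told apart here by chromosome.

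Differences were tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling factors, filterByExpr with its default minimum count of 10, a robust quasi-likelihood fit of 4 group means over all 8 libraries (4 residual degrees of freedom) and the quasi-likelihood F test. The filter kept 20508 genes and removed 10880. The common dispersion was 0.00816. P-values are two-sided and were adjusted by Benjamini-Hochberg over all genes tested, and a gene passed at an adjusted p under 0.05. The words rose, fell, higher and lower are used of genes and lists that passed. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of F. Levels are CPM (counts scaled to a common library size) after TMM, given as mean ± SD with n = 2. Of the 5 comparisons, 2 set IL4 against PBS in a fraction, 1 tests the difference of these 2 changes as an interaction, and 2 set GFP-positive against GFP-negative cells. Groups of 2 cannot reach a low p in a permutation test, and no other split of 2 against 2 was tested. Each group gave its own spread estimate through the shared fit only, and in fits without 1 library the lone library was assumed to vary like the other groups. Replicate numbers were not taken as pairs: the labels state no pairing, and the replicate deviations of any 2 groups correlated across genes by -0.011 to 0.0066.

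Ratios of counts at 1 to 3 counts in a group carry 95% counting intervals. Where a group had 0 counts, a bound was set at 3 counts over the group. These intervals and bounds cover counting error only, since amplified reads without molecular identifiers are not independent molecules. Shares of counts are given as descriptions of the libraries.

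Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01) on voom values, adjusted over the lists within a comparison, with camera at an estimated correlation and fry beside it. The 10 lists of cell-type markers were radial glia of the her4.1 lineage, neuron, oligodendrocyte and precursor, microglia and macrophage, neutrophil, lymphocyte, erythrocyte, endothelium, mural and fibroblast, and ependyma and motile cilia. The 23 other lists were the IL4 receptor and JAK-STAT6 pathway, serotonin synthesis, transport and receptors, neurotrophins and receptors, the NF-kB pathway, cell cycle and DNA replication, neurogenic and proneural genes, the Notch pathway, the Wnt pathway, FGF and ERK feedback, inflammatory cytokines and chemokines, interferon response, antigen presentation, immediate early and dissociation stress, heat shock, the unfolded protein response, cholesterol synthesis, the kynurenine pathway, p53 and apoptosis, glutamate and GABA receptors, extracellular matrix remodelling, ribosomal proteins, mitochondrially encoded genes, and nuclear oxidative phosphorylation genes. A member was matched by symbol without regard to case, then by a synonym, then by its name without the paralogue suffix. A matched symbol brought in every gene that carries it. Another 5 lists (pineal and photoreceptor genes, raphe serotonergic markers other than tph, circadian clock genes, hypothalamic neuropeptides, core microglia genes) were added after the data were seen and adjusted among themselves. No list was chosen by the study on these samples.

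The groups, comparisons, tests, the 33 lists, the alternatives other than library totals, and the rule for named genes were set before the data were examined. That rule names, per comparison, the 12 largest changes in each direction among genes that passed, had a mean of at least 5 CPM, had every library of one group above every library of the other and carried a symbol that is not a clone-type name (a clone prefix followed by digits), of which the text prints as many as it needs from the top. It also names 23 genes of the study question whatever their test says, and up to 4 members of each list with the smallest p. The gene il4r.2 was not found in the table. SE, adjusted p and the 2 libraries of each group stand behind every named gene, and for each called gene named both libraries of one group lay above both of the other in the IL4 and sort comparisons. A fold is given as the ratio of the larger to the smaller group.

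The procedure was tested on simulated counts drawn with the measured means, dispersions and library sizes for the same groups of 2. In GFP-positive cells it recovered 37.3% of genes changed by 1.5-fold, 73.1% at 2-fold and 93.9% at 4-fold, with 3.55% of 141 calls false. In GFP-negative cells it recovered 52.2%, 74.6% and 98.5%, with 7.41% of 162 calls false. The list shifted on purpose was called in both cases and 0 of 29 others were. Only 67, 67 and 66 genes were changed at these folds in a comparison, far fewer than passed in the data. Genes were drawn independently and lists at random. The simulation therefore cannot show how often the preset correlation calls a list whose members move together.

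Alternatives were RLE and upper-quartile scaling factors, the DESeq2 1.42.0 Wald test, limma voom, no filter beyond a total above 0, a stricter filter (50 counts in 2 libraries), the 4 libraries of a comparison alone, the replicate number as a block, a fit that is not robust, a log2 fold change of at least 1, and leaving out each library. Scaling by library totals was added after the data were seen. Very small adjusted p-values of the alternatives were set to a floor and rounded, as the most extreme varied with the number of threads. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The choice of named genes was shortened for length after values had been seen. At least the first gene of each ranking is printed. The words largest and most, used of genes, refer to that ranking.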

Results

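RNA sequencing counted reads over 31388 genes in 8 libraries from adult zebrafish brain. The brains had been injected with IL4, a cytokine that signals through its receptor and the transcription factor STAT6, or with PBS as the control. Cells were sorted by her4.1-driven GFP, which marks radial glia, the neural stem and progenitor cells of the fish brain. The 4 groups are PBS GFP-negative, PBS GFP-positive, IL4 GFP-negative and IL4 GFP-positive, with 2 libraries each. Per the title of the series, the study asked how IL4 acts on neural stem cells through serotonin and its HTR1 receptors, and on BDNF and the receptor NGFRA. Total counts ran from 19242851 to 26582271 per library, and 23243 to 25404 genes had at least 1 count. The most abundant transcript, malat1, took 14.5% to 20.5% of counts. Ribosomal protein genes took 2.37% to 4.17%, a share that was lower in GFP-negative than in GFP-positive libraries.

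The first principal component held 80.99% of the variance and separated GFP-positive from GFP-negative libraries. The second held 7.80% and separated IL4 from PBS, and the third held 4.15%. Replicates of a group correlated at 0.995 to 0.996 (Pearson, across genes, which are not independent replicates). Between groups of different fractions the correlation was 0.888 to 0.901, and between IL4 and PBS it was 0.986 in GFP-negative and 0.989 in GFP-positive cells. Replicates differed by more than counting error, with a chi-square per gene of 2.77 to 4.93.

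**Figure D1:**
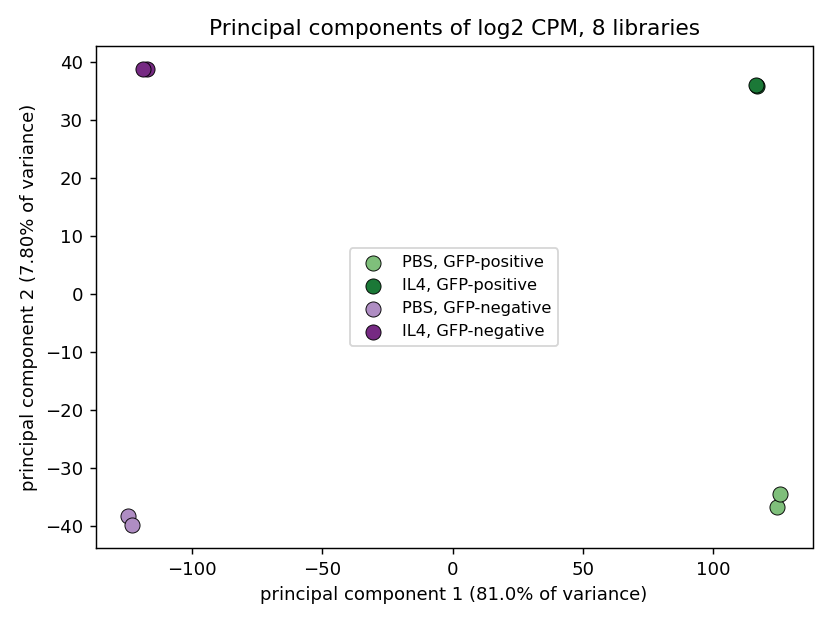
Principal components of log2 CPM for 8 libraries. The x axis (80.99% of variance) parts the GFP-positive from the GFP-negative libraries and the y axis (7.80%) parts IL4 from PBS, and the points are single libraries, coloured by group.

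The genes of the study question lie as follows on GRCz10. The IL4 receptor gene il4r.1 (ENSDARG00000102583) spans 43301383 to 43359120 on chromosome 3, and stat6 (ENSDARG00000015902) spans 27152325 to 27196639 on chromosome 23. TPH2 (ENSDARG00000057239), the serotonin-synthesizing tryptophan hydroxylase of the brain, spans 17000698 to 17011990 on chromosome 18. HTR1A, a serotonin receptor gene, lies on chromosome 21 (ENSDARG00000057098, 20913340 to 20914777). BDNF (ENSDARG00000018817), a neurotrophin gene, spans 31653833 to 31670520 on chromosome 7. Its receptor gene NTRK2 (ENSDARG00000059897) spans 49789717 to 49876606 on chromosome 8. The reporter's source gene her4.1 (ENSDARG00000056732) spans 21526006 to 21527063 on chromosome 23. PCNA (ENSDARG00000054155), a replication clamp, spans 40900618 to 40905471 on chromosome 10. The symbol NGFR belongs to a gene on chromosome 3 (ENSDARG00000088708) and one on chromosome 12 (ENSDARG00000089223), and the names used here do not say which of them is ngfra. TPH1 likewise names a gene on chromosome 7 (ENSDARG00000036082) and one on chromosome 25 (ENSDARG00000029432).

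**Figure D2:**
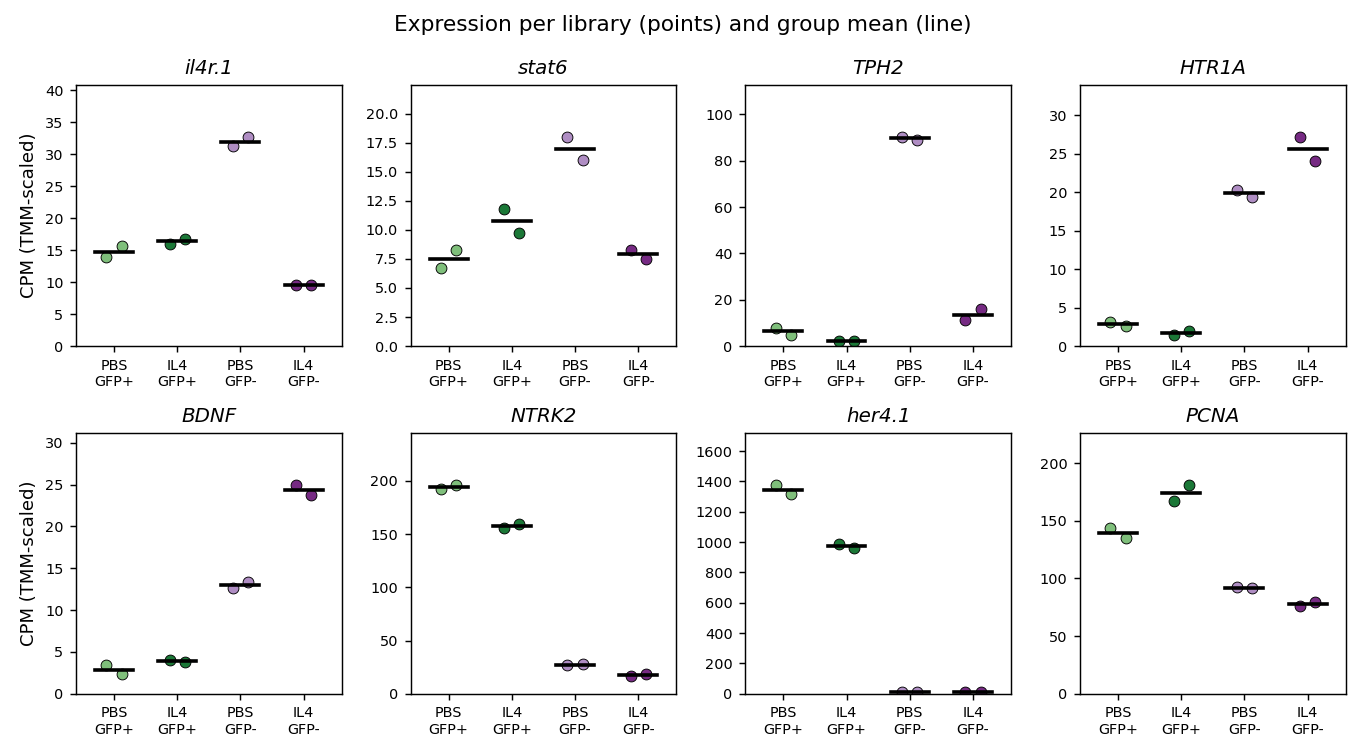
Expression of 8 question genes, in TMM-scaled CPM on the y axis, for each library (points) and group (line, the mean). The IL4 GFP-negative libraries lie below the PBS GFP-negative ones for il4r.1, stat6, TPH2, NTRK2 and PCNA and above them for BDNF and HTR1A, of which HTR1A did not pass.

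The first comparison set GFP-positive against GFP-negative cells after PBS, and it describes the sort. Radial glial genes were higher in GFP-positive cells. The reporter's source gene her4.1 was higher by 7.18 ± 0.07 (log2, SE, n = 2 against 2), at 1346 ± 43 against 9.25 ± 0.02 CPM. FABP7 (chromosome 17), a brain fatty acid-binding protein, was higher by 5.58 ± 0.04, the glial glutamate transporter SLC1A2 (ENSDARG00000102453) by 5.50 ± 0.04 and the gap junction gene GJA1 by 5.46 ± 0.04. Neuronal and myelin genes were lower, among them the synaptic gene SNAP25 (ENSDARG00000020609, -3.01 ± 0.04) and the myelin gene mbpa (-3.40 ± 0.04). The class II invariant chain cd74a was lower too (-3.54 ± 0.04), and immune and vascular lists were so at the preset correlation only, with values below. The largest differences were rx3, a homeobox gene (8.13 ± 0.20), arf4b (8.08 ± 0.08) and msrb2 (7.69 ± 0.14) on the higher side, and the globin genes HBE1 (ENSDARG00000089087, -7.49 ± 0.29) and hbaa1 (-6.84 ± 0.30) on the lower.

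In all, 14713 of 20508 genes differed after PBS, 6691 higher and 8022 lower in GFP-positive cells, and 3844 and 5863 by at least 2-fold. Library totals in place of TMM would shift the median of all genes by -0.484 and give 4231 higher and 10753 lower. Of 45 radial glial genes, 41 were higher and 2 lower, also adjusted over the list alone (median 4.24, adjusted p = 8.24e-25). Of 39 neuronal genes, 37 were lower, among them GAD2, which makes GABA, at -4.16 ± 0.08 (adjusted p = 3.95e-15). Of 17 oligodendrocyte genes 15 were lower (adjusted p = 4.7e-08). Of 35 Notch pathway genes, 25 were higher and 8 lower (median 1.74, adjusted p = 1.85e-06), and of 48 cell cycle genes 35 were higher (36 adjusted over the list alone, adjusted p = 3.48e-05). These 5 lists, and no other of the 33, also passed with an estimated correlation.

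The other lists called after PBS passed with the preset correlation only. Of 41 microglial genes 39 were lower, apoeb, an apolipoprotein E gene, at -3.06 ± 0.04 (adjusted p = 4e-17, and adjusted p = 0.0535 with an estimated correlation). Of 26 endothelial genes 22 were lower, the adhesion gene pecam1a at -4.16 ± 0.20 (adjusted p = 8.79e-05, and 0.0548 with an estimated correlation). Of 20 lymphocyte genes 17 were lower, tnfrsf9b at -4.92 ± 0.11 (adjusted p = 0.000256, and 0.067 with an estimated correlation). Of 8 neutrophil genes 7 were lower, the oxidase subunit NCF1 at -4.41 ± 0.11 (adjusted p = 0.00201, and 0.128). Of 14 ependymal genes 12 were higher, the ciliary regulator FOXJ1 by 2.85 ± 0.11 (adjusted p = 0.000256, and 0.0796). Serotonin genes (16 of 25 lower, median -2.17, adjusted p = 0.0213, and 0.119), glutamate and GABA receptors (39 of 45 lower, adjusted p = 8.1e-08, and 0.067) and antigen presentation (12 of 24 lower, adjusted p = 0.0252, and 0.18) were lower. Ribosomal proteins (78 of 80 higher, RPL19 by 1.06 ± 0.04, adjusted p = 9.36e-31, and 0.156), nuclear oxidative phosphorylation (93 of 103, adjusted p = 4.33e-21, and 0.128), mitochondrially encoded genes (12 of 13, adjusted p = 3.9e-07, and 0.201), heat shock (19 of 29, adjusted p = 0.000131, and 0.0796), cholesterol synthesis (19 of 29, adjusted p = 0.000579, and 0.0548) and the unfolded protein response (19 of 31, adjusted p = 0.000311, and 0.0548) were higher. So were immediate early genes (25 of 44, JDP2 by 4.02 ± 0.04, adjusted p = 0.000145, and 0.156) and FGF and ERK feedback (14 of 29, fgfbp3 by 7.26 ± 0.06, adjusted p = 0.016, and 0.18), each second p from an estimated correlation. Under library totals the medians of FGF feedback (0.29 to -0.19) and the unfolded protein response (0.44 to -0.04) changed sign. With 1 library left out the Wnt list passed without PBS GFP-positive replicate 1 (0.0246), and the mural list without PBS GFP-negative replicate 1 (0.0415), PBS GFP-positive replicate 1 (0.0439) or IL4 GFP-positive replicate 1 (0.0448) or 2 (0.0442).

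Most question genes were lower in GFP-positive cells after PBS: TPH2 by -3.82 ± 0.17, the serotonin receptor genes HTR1A by -2.80 ± 0.19, htr1aa by -2.27 ± 0.24 and htr1b by -2.73 ± 0.57, BDNF by -2.16 ± 0.20, il4r.1 by -1.11 ± 0.13 and stat6 by -1.19 ± 0.18. For htr1b the value was -5.32 without PBS GFP-positive replicate 1. NTRK2 was higher by 2.82 ± 0.07, GFAP by 6.19 ± 0.14, S100B by 5.43 ± 0.07, SOX2 by 3.49 ± 0.12 and PCNA by 0.60 ± 0.06. FABP7 of chromosome 20 was higher by 0.29 ± 0.11, a call that ended without PBS GFP-negative replicate 1 (0.30) or 2 (0.29). The proliferation gene mki67 was higher by 0.40 ± 0.14, a call that ended without PBS GFP-negative replicate 2 (0.28). Under library totals PCNA no longer passed (0.12), and FABP7 of chromosome 20 (-0.19) and mki67 (-0.08) turned sign. The serotonin transporter gene SLC6A4 had 0 counts in PBS GFP-positive and 27 in PBS GFP-negative libraries, at least 7.28-fold lower. TPH1 of chromosome 7 had 3 counts against 50, a ratio of 13.5 (counting interval 4.35 to 67.6), and TPH1 of chromosome 25 was lower by -3.77 ± 0.25. NGFR was lower on chromosome 3 (-0.81 ± 0.11) and chromosome 12 (-4.65 ± 0.67), and ntrk2b by -1.66 ± 0.20. HTR1D (-0.14 ± 0.30) did not pass and was 0.26 without PBS GFP-positive replicate 2.

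The sort comparison after IL4 again showed radial glial genes higher and neuronal genes lower in GFP-positive cells. The gene rx3 was higher by 8.65 ± 0.20, the retinoid isomerase gene RPE65 (ENSDARG00000054420) by 7.60 ± 0.21, the mitochondrial carrier UCP1 by 7.49 ± 0.10, GJA1 by 6.00 ± 0.05 and SLC1A2 (ENSDARG00000102453) by 5.83 ± 0.04. SNAP25 (ENSDARG00000020609) was lower by -3.41 ± 0.04, the myelin gene plp1b by -3.68 ± 0.03 and cd74a by -3.22 ± 0.04. In all, 13666 genes differed, 6642 higher and 7024 lower. Library totals would shift the median of all genes by -0.436 and give 4332 higher and 9833 lower. Of the 33 lists 22 passed, and 7 also with an estimated correlation: radial glia (41 of 45 higher), neuron (37 of 39 lower), oligodendrocyte (14 of 17 lower), cell cycle (39 of 48 higher), Notch (26 of 35 higher), the unfolded protein response (23 of 31 higher) and cholesterol synthesis (23 of 29 higher). The Wnt pathway (19 of 37 higher, adjusted p = 0.00247, and 0.0571 with an estimated correlation), the interferon response (21 of 33 higher, adjusted p = 0.00135, and 0.0571) and p53 and apoptosis (17 of 32 higher, adjusted p = 0.0476, and 0.135) passed after IL4 with the preset correlation only. So did serotonin genes (14 of 25 lower, adjusted p = 0.0476, and 0.135), and the p53 and serotonin calls ended without IL4 GFP-positive replicate 1 (adjusted p = 0.0618 each). Under library totals the p53 median of 0.34 was -0.10. Heat shock (median 0.14, and -0.30 under library totals) did not pass, although it did without IL4 GFP-negative replicate 1 (0.0466). Among the lower of the largest differences, PMCH, a neuropeptide gene, had 2 counts against 779, a ratio of 306 (counting interval 84.5 to 2532).

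Question genes after IL4 differed between the fractions as follows. TPH2 was lower in GFP-positive cells by -2.70 ± 0.23, HTR1A by -3.88 ± 0.20, htr1aa by -2.43 ± 0.25, htr1b by -3.97 ± 0.66, BDNF by -2.63 ± 0.19 and NGFR of chromosome 3 by -1.05 ± 0.12. The IL4 receptor gene il4r.1 was higher by 0.77 ± 0.14 and NTRK2 by 3.14 ± 0.08, her4.1 by 6.65 ± 0.06, GFAP by 5.78 ± 0.14, S100B by 4.95 ± 0.07, FABP7 by 5.46 ± 0.04 (chromosome 17) and 0.94 ± 0.12 (chromosome 20), SOX2 by 2.76 ± 0.12, PCNA by 1.16 ± 0.06 and mki67 by 1.05 ± 0.14. The higher value of stat6 (0.45 ± 0.18) lost its call without PBS GFP-negative replicate 1 (0.45), IL4 GFP-negative replicate 1 (0.52) or 2 (0.38), or IL4 GFP-positive replicate 1 (0.32), under RLE factors, in DESeq2, without a filter and under library totals. SLC6A4 had 3 counts in GFP-positive against 21 in GFP-negative libraries, a ratio of 5.50 (counting interval 1.64 to 28.8). Its fitted value lost its call without IL4 GFP-negative replicate 1 (-2.34) or 2 (-2.42) and without IL4 GFP-positive replicate 1 (-1.97) or 2 (-2.92), and in DESeq2. TPH1 was lower on chromosome 7 (-2.18 ± 0.56) and chromosome 25 (-3.06 ± 0.28), and ntrk2b by -1.57 ± 0.19. HTR1D (-0.32 ± 0.31) and NGFR of chromosome 12 (-1.31 ± 0.66) did not pass. HTR1D was 0.03 without IL4 GFP-positive replicate 2 and passed under library totals (-0.75), and NGFR of chromosome 12 passed at -8.13 without IL4 GFP-positive replicate 1, and in voom, with the replicate block and under library totals.

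In GFP-positive cells neurogenic genes rose and radial glial genes fell after IL4. Microglial and oxidative phosphorylation genes fell too, as lists at the preset correlation (adjusted p = 0.0685 and 0.0672 with an estimated one). Of the neurogenic list, the transcription factor genes EBF3 and NEUROD1 rose by 1.60 ± 0.09 and 0.79 ± 0.05 (log2, SE, n = 2 against 2), and the tubulin gene tubb5 by 0.97 ± 0.04. ELAVL3, an RNA-binding protein gene of young neurons from the neuronal list, rose by 1.30 ± 0.04. Among radial glial genes ID1, a target of BMP signalling, fell by -0.92 ± 0.05, cspg5b by -0.87 ± 0.05, mfge8a by -0.68 ± 0.04 and her4.1 by -0.46 ± 0.05. Among the genes ranked the largest rises were those of GEM, a small GTPase gene (2.68 ± 0.26), and of the phosphodiesterase gene pde4cb (2.52 ± 0.60), and the largest fall was that of the neuropeptide gene oxt (-6.43 ± 0.15), from 126 to 1.46 CPM. The pde4cb call ended without PBS GFP-positive replicate 1 (1.59) or IL4 GFP-positive replicate 1 (1.79), and the value was 4.44 without PBS GFP-positive replicate 2. In all, 5889 of 20508 genes changed, 2847 higher and 3042 lower, and 662 and 605 by at least 2-fold. Under RLE factors 2465 of 6048 were higher, and under library totals 3476 of 5886.

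Of 41 neurogenic and proneural genes 29 rose and 0 fell, also adjusted over the list alone. The median was 0.79 (adjusted p = 8.13e-15, and 0.0217 with an estimated correlation). Of 39 neuronal genes 17 rose and 3 fell (19 and 4 adjusted over the list alone), with ELAVL4 at 0.67 ± 0.05. The neuronal list passed at adjusted p = 0.00028, and 0.0672 with an estimated correlation. Of 45 radial glial genes 24 fell and 4 rose (27 and 5 adjusted over the list alone). The median was -0.20 (adjusted p = 1.16e-11, and 0.0389 with an estimated correlation). Notch pathway genes split into 16 lower, her8a at -0.89 ± 0.11, and 9 higher of 35 (16 and 10 adjusted over the list alone, adjusted p = 0.0496, and 0.158 with an estimated correlation). The Notch median of -0.07 was 0.002 under library totals, and its call ended without IL4 GFP-negative replicate 1 (0.0641) or 2 (0.0643) and with the replicate number as a block (adjusted p = 0.0587). Of 48 cell cycle genes 11 rose and 1 fell, the cyclin gene CCND1 by 0.62 ± 0.09 (11 and 1 adjusted over the list alone, adjusted p = 0.0266, and 0.123 with an estimated correlation, the call ending without PBS GFP-positive replicate 1 at 0.0545).

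Interferon response genes rose in 16 of 33 cases (20 adjusted over the list alone), the RNA sensor DHX58 by 1.90 ± 0.16 and the antiviral gene RSAD2 by 1.01 ± 0.09 (adjusted p = 1.98e-07, and 0.0363 with an estimated correlation). Cholesterol synthesis genes rose in 16 of 29 cases and 0 fell (16 and 1 adjusted over the list alone), the receptor gene ldlra by 1.87 ± 0.13 and the synthase gene HMGCS1 by 0.84 ± 0.07 (adjusted p = 3.93e-08, and 0.0363). Nuclear oxidative phosphorylation genes fell in 92 of 103 cases (95 adjusted over the list alone), atp5if1b by -0.88 ± 0.06, COX7C by -0.81 ± 0.05 and ATP5MG by -0.73 ± 0.05 (median -0.60, adjusted p = 2.57e-47, and 0.0672 with an estimated correlation). Random lists matched to these genes on length and mean expression had a median of -0.33. Part of this fall may be such a trend, untested for radial glial genes. The 13 mitochondrially encoded genes had a median of 0.0003, which was -0.05 under RLE factors, with a mean of -0.06 and no call, although the list passed without PBS GFP-positive replicate 2 (adjusted p = 0.0182). Ribosomal protein genes fell in 42 of 80 cases and rose in 4 (47 and 4 adjusted over the list alone, adjusted p = 1.42e-09, 0.533 with an estimated correlation and 0.119 in fry). Heat shock genes fell in 17 of 29 cases and rose in 5 (17 and 5 adjusted over the list alone), hsp70.1 by -1.62 ± 0.04, hsp70l by -1.15 ± 0.03 and HSPB1 by -1.20 ± 0.04 (adjusted p = 5.69e-09, and 0.0578).

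Markers of other cell types moved too, and whether these transcripts come from radial glia or from other cells in the fraction was not tested. Microglial genes fell in 31 of 41 cases and 0 rose (31 and 1 adjusted over the list alone, median -1.08), the apolipoprotein E gene apoeb by -1.82 ± 0.04 and cd74a by -1.02 ± 0.04 (adjusted p = 1.16e-11, and 0.0685 with an estimated correlation). Oligodendrocyte genes fell in 9 of 17 cases and 1 rose (10 and 1 adjusted over the list alone), cd59a by -0.79 ± 0.03 and plp1b by -0.44 ± 0.03 (adjusted p = 0.000439, and 0.0672). Inflammatory cytokine and chemokine genes fell in 19 of 40 cases and 4 rose (19 and 6 adjusted over the list alone), cxcl18b by -0.83 ± 0.05 and CXCL14 by -0.78 ± 0.05 (adjusted p = 0.00338, and 0.152). Immediate early genes fell in 24 of 44 cases and 11 rose (25 and 11 adjusted over the list alone), the phosphatase gene DUSP2 by -1.05 ± 0.06, while NPAS4 rose by 0.80 ± 0.05 (adjusted p = 5.95e-06, and 0.177). Kynurenine pathway genes fell in 4 of 10 cases (4 adjusted over the list alone, adjusted p = 0.0245, and 0.222 with an estimated correlation, the call ending without PBS GFP-positive replicate 1 at 0.0545). Erythrocyte genes (1 of 12 fell, median -0.32, or -0.22 with members at 0 counts set to their bound), endothelial (4 of 26 fell and 3 rose), lymphocyte (4 of 20 rose and 1 fell), neutrophil (1 of 8 rose and 2 fell), mural (3 of 21 rose and 3 fell) and ependymal lists (1 of 14 fell) did not pass. Nor did the IL4 receptor and JAK-STAT6 list, with a median of 0.20 and a mean of -0.09 (11 of 31 rose and 6 fell, JAK1 by 0.76 ± 0.07 and the feedback gene SOCS3 by 0.39 ± 0.05 upward). The NF-kB list (6 of 25 rose and 6 fell), neurotrophin (4 of 21 rose and 1 fell), serotonin (3 of 25 rose and 2 fell), antigen presentation (6 of 24 rose and 3 fell), glutamate and GABA receptor (8 of 45 rose and 3 fell) and extracellular matrix lists (11 of 46 rose and 6 fell) did not pass either. The Wnt median of 0.01 (mean 0.09, 11 of 37 rose and 7 fell), the FGF median of -0.003 (0.001 under upper-quartile factors, mean 0.07, 7 of 29 rose and 5 fell), the unfolded protein response median of -0.05 (4 of 31 rose and 8 fell) and the p53 median of -0.05 (6 of 32 rose and 7 fell) did not pass and changed sign under a scaling, to -0.05 (RLE), 0.07, 0.03 and 0.03 (library totals) in that order. Of these the unfolded protein response passed without IL4 GFP-positive replicate 1 (adjusted p = 0.0366).

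Question genes in GFP-positive cells went both ways after IL4. TPH2 fell by -1.60 ± 0.25, NTRK2 by -0.30 ± 0.06, S100B by -0.39 ± 0.06 and FABP7 by -0.56 ± 0.04 (chromosome 17) and -0.55 ± 0.12 (chromosome 20). After PBS, TPH2 stood at 7.73 and 4.86 CPM in GFP-positive libraries, against 90.2 and 89.0 in GFP-negative ones. The pineal gene ASMT likewise stood at 11.7 against 170. Whether the few TPH2 transcripts of this fraction come from radial glia was not tested. PCNA rose by 0.32 ± 0.06, from 139 ± 5.7 to 174 ± 10.1 CPM, and mki67 by 0.52 ± 0.14. PCNA did not pass without IL4 GFP-positive replicate 2 (0.20), nor mki67 without PBS GFP-positive replicate 2 (0.44), IL4 GFP-positive replicate 1 (0.45) or 2 (0.48). The rise of stat6 (0.53 ± 0.19, adjusted p = 0.0386) ended in each fit without 1 library except that without PBS GFP-positive replicate 2, at values of 0.33 to 0.60, under RLE factors, in DESeq2 and with the 4 libraries alone. HTR1A fell by -0.72 ± 0.25 (adjusted p = 0.0374), a call that ended without PBS GFP-positive replicate 1 (-0.65), IL4 GFP-positive replicate 1 (-0.57) or either IL4 GFP-negative library (-0.72), in voom, with the 4 libraries alone and under library totals. TPH1 of chromosome 7 had 16 counts after IL4 against 3, a ratio of 6.00 (counting interval 1.72 to 32.2). Its fitted rise of 2.49 ± 0.90 passed (adjusted p = 0.0444) but failed in each fit without 1 library except that without IL4 GFP-positive replicate 1, at values of 1.77 to 2.49 in most and 3.06 without PBS GFP-positive replicate 2. It failed too in DESeq2, in voom and with the 4 libraries alone. SLC6A4 had 3 counts after IL4 and 0 after PBS, too few for a fold. The IL4 receptor gene il4r.1 (0.15 ± 0.14), BDNF (0.43 ± 0.23), htr1aa (-0.20 ± 0.29), NGFR of chromosome 3 (-0.07 ± 0.12), SOX2 (-0.19 ± 0.10) and HTR1D (-0.01 ± 0.31) did not pass, and HTR1D was 0.36 without PBS GFP-positive replicate 1 and 0.27 without IL4 GFP-positive replicate 2. Calls appeared with 1 library left out for GFAP (-0.22 ± 0.09, and -0.22 without either PBS GFP-negative library, as also under RLE factors, in voom, without a filter and with the 4 libraries alone), ntrk2b (0.38 ± 0.21, and 0.66 without PBS GFP-positive replicate 2), TPH1 of chromosome 25 (-0.58 ± 0.34, -1.11 without PBS GFP-positive replicate 1 and 0.01 without replicate 2), htr1b (-1.10 ± 0.86, -1.98 without PBS GFP-positive replicate 2 and 1.51 without replicate 1) and NGFR of chromosome 12 (1.22 ± 0.88, 2.15 without IL4 GFP-positive replicate 2 and -5.66 without replicate 1).

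After IL4, microglial, endothelial and matrix genes were lower and neuronal genes higher in GFP-negative cells. This fraction mixes cell types and levels are shares of counts. Changes in cell numbers were therefore not told apart from changes in expression, for the falls and the rises alike. The microglial gene apoeb fell by -2.31 ± 0.04 (log2, SE, n = 2 against 2), lgals3bp.1 by -2.32 ± 0.06 and cd74a by -1.35 ± 0.04. The endothelial genes pecam1a, flt1 and kdrl, of which flt1 and kdrl encode VEGF receptors, fell by -2.41 ± 0.17, -2.04 ± 0.18 and -1.88 ± 0.17. The neuronal genes RBFOX3, ELAVL3 and STMN1 rose by 1.23 ± 0.07, 0.66 ± 0.04 and 0.52 ± 0.03. The largest falls were those of aanat2, which makes the precursor of melatonin (-6.02 ± 0.15), the collagen gene COL10A1 (ENSDARG00000101535, -5.53 ± 0.23) and the photoreceptor regulator NR2E3 (-4.64 ± 0.20). The largest rises were those of cldna, a claudin gene (1.67 ± 0.16), rorcb (1.59 ± 0.28) and the keratin gene krt91 (1.58 ± 0.10). In all, 5016 genes changed, 1853 higher and 3163 lower, and 197 and 1387 by at least 2-fold. Under upper-quartile factors 2367 of 5224 were higher. The number of genes changed by IL4 in GFP-negative cells was 3244 without IL4 GFP-negative replicate 1 and 3195 without replicate 2.

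Microglial genes fell in 36 of 41 cases (37 adjusted over the list alone, median -1.39, adjusted p = 4.53e-42, and adjusted p = 0.0144 with an estimated correlation). Endothelial genes fell in 21 of 26 cases (22 adjusted over the list alone, median -1.28, adjusted p = 2.6e-14, and 0.0144). Extracellular matrix genes fell in 23 of 46 cases with 1 rise (27 and 1 adjusted over the list alone, adjusted p = 9.39e-07, and 0.0171), the matrix gene SPARC by -1.29 ± 0.08 and the inhibitor gene TIMP4 by -1.04 ± 0.08. Mural and fibroblast genes fell in 9 of 21 cases, COL1A2 by -2.56 ± 0.14 (9 adjusted over the list alone, adjusted p = 0.000868, and 0.0844 with an estimated correlation). Unfolded protein response genes fell in 19 of 31 cases and 2 rose, the chaperone gene HSPA5 by -1.12 ± 0.04 and slc3a2a by -1.61 ± 0.06 (19 and 2 adjusted over the list alone, adjusted p = 6e-09, and 0.0155). Neuronal genes rose in 22 of 39 cases and 0 fell (24 and 1 adjusted over the list alone, adjusted p = 1.98e-18, and 0.0144). Neurogenic genes rose in 21 of 41 cases and 4 fell, NEUROD1 by 0.59 ± 0.04, tubb5 by 0.58 ± 0.04 and ZIC1 by 0.59 ± 0.05 upward (24 and 4 adjusted over the list alone, adjusted p = 1.32e-09, and 0.0144). Oligodendrocyte genes rose in 9 of 17 cases and 4 fell, cd59a by 0.64 ± 0.03 and plp1b by 0.47 ± 0.03 upward (11 and 4 adjusted over the list alone, adjusted p = 6.54e-08, and 0.0171). These 7 lists other than the mural one passed with both correlations.

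Inflammatory genes fell in 21 of 40 cases and 3 rose in GFP-negative cells, the chemokine gene cxcl8b.1 by -2.27 ± 0.13, csf3b by -3.24 ± 0.22 and the heme oxygenase gene HMOX1 by -2.39 ± 0.07 (21 and 3 adjusted over the list alone, adjusted p = 1.38e-06, and 0.0556 with an estimated correlation). Antigen presentation genes fell in 8 of 24 cases, mhc2dab by -1.15 ± 0.06 (9 adjusted over the list alone, adjusted p = 0.000114, and 0.0844). NF-kB genes fell in 10 of 25 with 2 rises, NFKBIE by -0.86 ± 0.08 (12 and 2 adjusted over the list alone, adjusted p = 0.00376, and 0.0827). Neutrophil genes fell in 5 of 8 cases and 1 rose (6 and 2 adjusted over the list alone, adjusted p = 0.0209, and 0.226). IL4 receptor and JAK-STAT6 genes fell in 9 of 31 cases and 2 rose, il13ra1, a receptor chain gene, by -1.16 ± 0.10 and SOCS3 by -0.78 ± 0.06 (10 and 3 adjusted over the list alone, adjusted p = 0.021, and 0.226), a call that ended without PBS GFP-negative replicate 1 (0.0772). Interferon response genes rose in 10 of 33 cases and 2 fell, isg15 by 0.80 ± 0.07 and RSAD2 by 1.13 ± 0.10 (11 and 2 adjusted over the list alone, adjusted p = 0.0017, and 0.0652). Immediate early genes fell in 21 of 44 cases and 9 rose, JDP2 by -1.02 ± 0.04 and DUSP1 by -1.29 ± 0.06 (23 and 9 adjusted over the list alone, adjusted p = 2.77e-05, and 0.172). Wnt genes fell in 12 of 37 cases and 2 rose (16 and 3 adjusted over the list alone, adjusted p = 0.0076, and 0.0829). Ribosomal protein genes fell in 77 of 80 cases, rps20 by -0.47 ± 0.04 (77 adjusted over the list alone, adjusted p = 1.01e-32, and 0.195). Mitochondrially encoded genes fell in 11 of 13 (12 adjusted over the list alone, adjusted p = 5.76e-06, and 0.308), as did oxidative phosphorylation genes in 20 of 103 with 1 rise (18 and 1 adjusted over the list alone, adjusted p = 0.0209, 0.677 with an estimated correlation and 0.116 in fry). The last call ended without PBS GFP-negative replicate 2 (0.572) and without IL4 GFP-positive replicate 1 (0.0522) or 2 (0.0522).

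Radial glial genes split evenly in GFP-negative cells, 13 higher and 14 lower of 45, with a median of 0.03, a mean of -0.19 and no call. Cell cycle genes (8 of 48 fell, MCM2 by -0.96 ± 0.12), Notch (7 of 35 rose and 8 fell), FGF (1 of 29 rose and 8 fell), p53 (3 of 32 rose and 12 fell), cholesterol synthesis (2 of 29 rose and 2 fell, HMGCS1 by -1.18 ± 0.07), kynurenine (2 of 10 fell), erythrocyte (1 of 12 rose and 3 fell), lymphocyte (4 of 20 rose and 4 fell, median 0.27) and glutamate and GABA receptor lists (6 of 45 rose and 5 fell) did not pass. Heat shock genes (6 of 29 rose and 9 fell, hsp70.1 by -0.45 ± 0.04 and HSPB1 by -1.11 ± 0.05) had a median of -0.04 that was 0.01 under upper-quartile factors. Ependymal genes (5 of 14 fell, 8 adjusted over the list alone) passed as a list only without PBS GFP-negative replicate 2 (0.043) or IL4 GFP-negative replicate 2 (0.036). Serotonin genes fell in 5 of 25 cases and 0 rose (5 adjusted over the list alone), DDC, which makes serotonin from its precursor, by -1.78 ± 0.17 and GCH1 by -1.34 ± 0.15. The list did not pass (adjusted p = 0.529), and its median of -0.01 was 0.002 under RLE, 0.04 under upper-quartile factors and 0.01 under library totals. The neurotrophin list had a median of 0.04 and a mean of -0.03 and did not pass (3 of 21 rose and 4 fell).

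**Figure D3:**
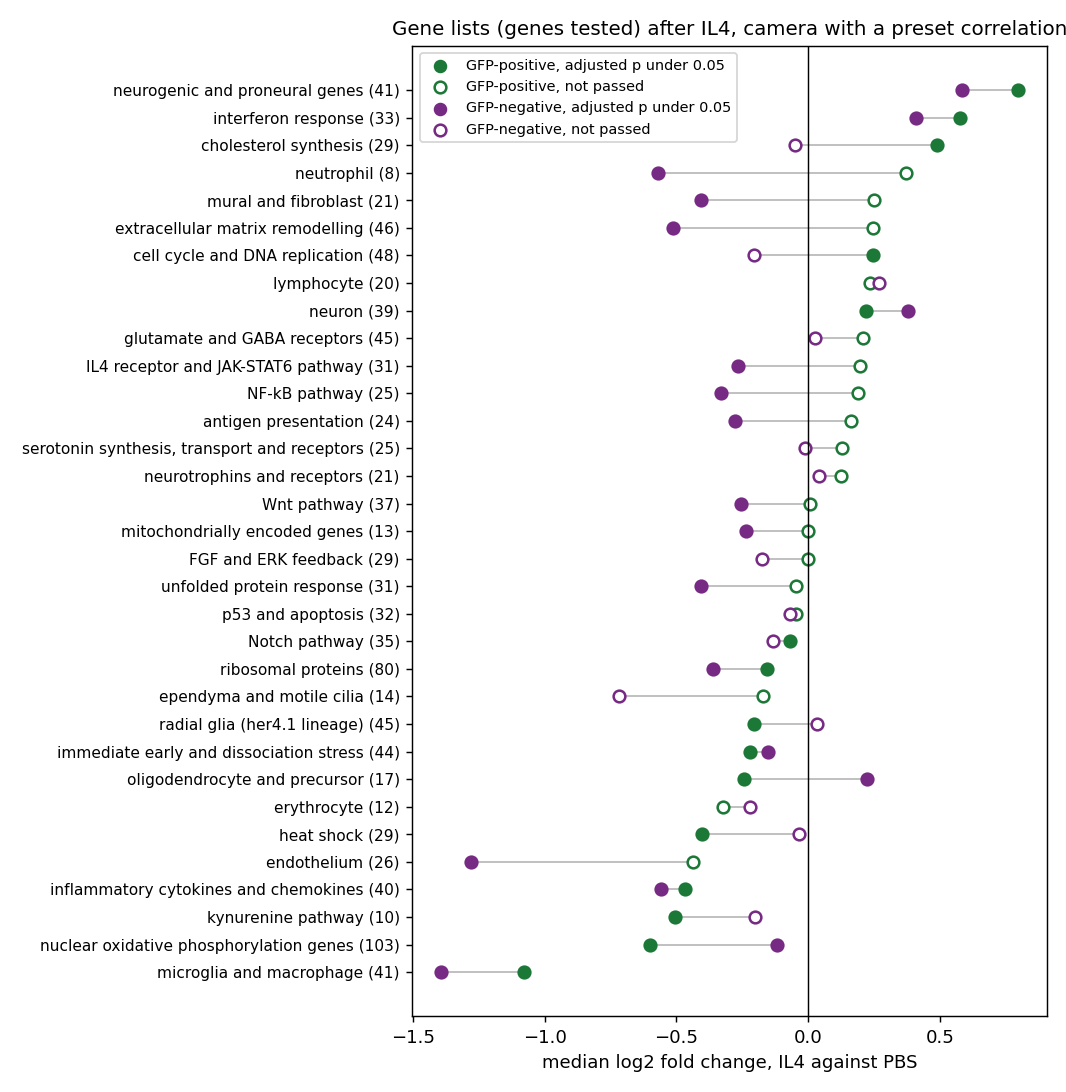
Median log2 fold change after IL4 against PBS (x axis) of each of 33 gene lists (y axis, with the number of genes tested), in GFP-positive (green) and GFP-negative (purple) cells, with filled points where camera at the preset correlation passed. Microglial genes are lowest in both fractions (-1.08 and -1.39) and neurogenic genes highest (0.79 and 0.58).

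Of the question genes in GFP-negative cells, TPH2 fell by -2.72 ± 0.15, from 89.6 ± 0.8 to 13.6 ± 3.1 CPM, TPH1 of chromosome 25 by -1.29 ± 0.20, il4r.1 by -1.73 ± 0.14, from 32.0 ± 1.0 to 9.62 ± 0.002 CPM, and stat6 by -1.11 ± 0.18. BDNF rose by 0.90 ± 0.17 (adjusted p = 0.00033), from 13.03 ± 0.5 to 24.4 ± 0.9 CPM. NTRK2 fell by -0.62 ± 0.08 and FABP7 by -1.20 ± 0.12 (chromosome 20) and -0.44 ± 0.04 (chromosome 17, not in voom). SOX2, a progenitor transcription factor, rose by 0.54 ± 0.14, a call that ended without PBS GFP-negative replicate 1 (0.38). PCNA fell by -0.24 ± 0.06. That call ended without IL4 GFP-negative replicate 1 (-0.20). NGFR of chromosome 12 fell by -2.12 ± 0.51, which ended without PBS GFP-negative replicate 1 (-1.88), without IL4 GFP-negative replicate 2 (-1.88) and in DESeq2. HTR1A (0.37 ± 0.15) passed only without either PBS GFP-positive library (0.39), under upper-quartile factors, in voom and with the 4 libraries alone. TPH1 of chromosome 7 (1.02 ± 0.49, which passed with the 4 libraries alone), NGFR of chromosome 3 (0.16 ± 0.11), ntrk2b (0.28 ± 0.18) and SLC6A4 (-0.23 ± 0.64, 21 counts against 27) did not pass. Others that did not pass changed sign with 1 library left out: GFAP (0.19 ± 0.22, -0.13 without PBS GFP-negative replicate 2 and -0.19 without IL4 GFP-negative replicate 1), htr1aa (-0.03 ± 0.21, 0.19 without PBS GFP-negative replicate 2 and 0.05 without IL4 GFP-negative replicate 1), her4.1 (0.07 ± 0.08, -0.05 without IL4 GFP-negative replicate 1), mki67 (-0.13 ± 0.15, 0.01 without PBS GFP-negative replicate 1), S100B (0.09 ± 0.09), htr1b (0.13 ± 0.45) and HTR1D (0.16 ± 0.30). Without IL4 GFP-negative replicate 2 the last 3 were -0.03, -0.08 and -0.12.

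The last comparison tested whether the change after IL4 differed between the fractions, with positive values where it was higher in GFP-positive cells. It differed for 3843 genes, 2355 higher and 1488 lower, although under RLE factors 1941 of 3791 were higher and without IL4 GFP-negative replicate 1 the count was 2509. COL10A1 (ENSDARG00000101535) differed most on the higher side among named genes with a mean of at least 5 CPM (5.21 ± 0.69), followed there by the sialomucin gene podxl (3.06 ± 0.15). On the lower side PMCH, a neuropeptide gene, had 2 counts in IL4 GFP-positive libraries against 58 after PBS, a ratio of 25.8 (counting interval 6.82 to 218), and oxt differed by -4.24 ± 0.20. HMGCS1 (2.02 ± 0.10) and ldlra (2.09 ± 0.20) were higher, and the myelin genes cd59a (-1.43 ± 0.05) and plp1b (-0.91 ± 0.04) were lower.

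Of the 33 lists 20 differed between the fractions. Oligodendrocyte genes (10 of 17 lower and 2 higher, 10 and 3 adjusted over the list alone, adjusted p = 3.28e-09), the unfolded protein response (15 of 31 higher and 1 lower, 17 and 2 adjusted over the list alone, HSPA5 by 1.14 ± 0.05 and slc3a2a by 1.09 ± 0.08, adjusted p = 1.01e-07) and the extracellular matrix (23 of 46 higher, 27 adjusted over the list alone, TIMP4 by 1.27 ± 0.10 and TIMP2 by 0.91 ± 0.09, adjusted p = 1.01e-07) also passed with an estimated correlation, each at 0.0345. Oxidative phosphorylation genes were lower in 74 of 103 cases (81 adjusted over the list alone), atp5if1b by -0.98 ± 0.08 (adjusted p = 1.76e-37, and adjusted p = 0.0847 with an estimated correlation). Heat shock genes were lower in 14 of 29 with 6 higher, hsp70.1 by -1.17 ± 0.05 (15 and 6 adjusted over the list alone, adjusted p = 3.42e-08, and 0.0561). Cell cycle genes were higher in 10 of 48 cases and 1 lower, MCM2 by 1.27 ± 0.16 and MCM5 by 1.74 ± 0.24 (11 and 1 adjusted over the list alone, adjusted p = 0.0062, and 0.0847). Neurogenic genes were higher in 13 of 41 and 1 lower, ascl1a by 1.36 ± 0.14 (14 and 1 adjusted over the list alone, adjusted p = 0.00239, and 0.0781). ELAVL3 of the neuronal list was higher by 0.64 ± 0.06, although that list was lower (median -0.10). IL4 receptor and JAK-STAT6 genes were higher in 9 of 31 cases and 2 lower, SOCS3 by 1.17 ± 0.08 and il13ra1 by 1.52 ± 0.14 (10 and 2 adjusted over the list alone, adjusted p = 0.0161, and 0.148), a call that ended without IL4 GFP-positive replicate 1 (0.0614). Cell-type markers differed too: microglial genes were higher in 16 of 41 cases (17 adjusted over the list alone, adjusted p = 0.0161, and 0.363). Endothelial genes were higher in 9 of 26 cases (9 adjusted over the list alone, adjusted p = 0.0062, and 0.0847) and mural genes in 7 of 21 (8 adjusted over the list alone, adjusted p = 0.00265, and 0.11). The Notch list had a median of 0.14 with a test in the lower direction, and the lymphocyte list a median of 0.03, a mean of -0.05 and medians of -0.04 and -0.02 under RLE and upper-quartile factors, and neither passed. Neutrophil genes passed only without PBS GFP-positive replicate 2 (0.0441) and in fry (0.0343).

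Among question genes, the difference passed for il4r.1 (1.88 ± 0.19, adjusted p = 8.01e-07), stat6 (1.64 ± 0.26, adjusted p = 0.000121), PCNA (0.56 ± 0.09), SOX2 (-0.73 ± 0.17), her4.1 (-0.53 ± 0.09) and S100B (-0.48 ± 0.10), the last pair not in voom. TPH2 (1.12 ± 0.31) lost its call without PBS GFP-positive replicate 2 (0.76), IL4 GFP-negative replicate 1 (0.90) and IL4 GFP-positive replicate 1 (0.97) or 2 (1.11). HTR1A (-1.09 ± 0.29) lost it without IL4 GFP-negative replicate 1 (-0.997) or IL4 GFP-positive replicate 1 (-0.96) and in voom, and FABP7 of chromosome 20 (0.65 ± 0.17) without IL4 GFP-negative replicate 2 (0.54) or IL4 GFP-positive replicate 1 (0.54). NTRK2 (0.32 ± 0.10) kept its call without PBS GFP-negative replicate 1 or IL4 GFP-negative replicate 2 and lost it without PBS GFP-negative replicate 2 (0.29), PBS GFP-positive replicate 1 (0.23) or 2 (0.26), IL4 GFP-negative replicate 1 (0.24) and IL4 GFP-positive replicate 1 (0.26) or 2 (0.22). It lost it also under RLE and upper-quartile factors, in DESeq2 and in voom. Among the fits without 1 library the call of mki67 (0.65 ± 0.20) held without PBS GFP-negative replicate 2 alone, and it ended without PBS GFP-negative replicate 1 (0.50), PBS GFP-positive replicate 1 (0.60) or 2 (0.55), IL4 GFP-negative replicate 1 (0.57) or 2 (0.73) and IL4 GFP-positive replicate 1 (0.56) or 2 (0.59), under RLE factors and in DESeq2. NGFR of chromosome 12 (3.34 ± 1.01) turned to -3.55 without IL4 GFP-positive replicate 1 and lost its call without PBS GFP-negative replicate 1 (3.10), PBS GFP-positive replicate 2 (2.82) or IL4 GFP-negative replicate 2 (3.10), in DESeq2, in voom and without a filter. BDNF (-0.47 ± 0.28, adjusted p = 0.273), TPH1 of chromosome 7 (1.48 ± 1.04), NGFR of chromosome 3 (-0.24 ± 0.16) and SLC6A4 (adjusted p = 0.193) did not pass. GFAP (-0.41 ± 0.24) passed only without PBS GFP-negative replicate 1 (-0.83), TPH1 of chromosome 25 (0.71 ± 0.40) without PBS GFP-positive replicate 2 (1.28), and FABP7 of chromosome 17 (-0.12 ± 0.05) without PBS GFP-negative replicate 2 (-0.18), PBS GFP-positive replicate 2 (-0.23) or IL4 GFP-positive replicate 2 (-0.21), under RLE and upper-quartile factors and in DESeq2. Some that did not pass changed sign with 1 library left out: htr1b (-1.23 ± 0.97, 1.36 without PBS GFP-positive replicate 1), htr1aa (-0.16 ± 0.36, 0.03 without PBS GFP-negative replicate 1), ntrk2b (0.10 ± 0.28, -0.27 without PBS GFP-positive replicate 1 and -0.14 without IL4 GFP-positive replicate 1) and HTR1D (-0.18 ± 0.43, 0.18 without PBS GFP-positive replicate 1, 0.10 without IL4 GFP-negative replicate 2 and 0.09 without IL4 GFP-positive replicate 2).

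Genes changed by IL4 in both fractions overlapped more than independence would give. Of those, 801 were higher in both (257.2 by independence) and 1090 lower in both (469.2). By contrast, 284 were higher in GFP-positive and lower in GFP-negative cells (439.1) and 170 the reverse (274.9). ELAVL3, NEUROD1, tubb5 and RSAD2 were among those higher in both, and apoeb, cd74a, TPH2 and NTRK2 among those lower in both. Of these, apoeb, cd74a and TPH2 were far lower in GFP-positive than in GFP-negative cells after PBS. Whether any named gene changed in radial glia was not tested. Across genes the log2 fold changes of the fractions correlated at 0.267 (Pearson) and 0.251 (Spearman), and at 0.422 and 0.328 in the 12636 genes with at least 5 CPM, with genes not being independent replicates.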

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

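Of the tests in this part, those on pineal genes, on raphe neurons as the whole cause, on a lower yield of all non-neural cells and on the share of mitochondrial RNA were chosen after the result was seen, as was 1 condition of the microglia test, named below.

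Each result in this paragraph and the next 3 stands here because an interaction test found its change after IL4 to differ between GFP-positive and GFP-negative cells. The test passed for 3843 genes, or 2509 without IL4 GFP-negative replicate 1. It passed for 20 lists at the preset correlation, of which oligodendrocyte (-0.46), unfolded protein response (0.43) and extracellular matrix (0.74) also passed at an estimated correlation (adjusted p = 0.0345 each). The medians of the other lists with more positive values in GFP-positive cells were microglia 0.43, endothelium 0.69, mural 0.86, IL4 receptor and JAK-STAT6 0.34, NF-kB 0.35, cell cycle 0.39, neurogenic 0.39, Wnt 0.35, antigen presentation 0.42, cholesterol synthesis 0.51, ribosomal proteins 0.23 and mitochondrially encoded genes 0.23. Those with more negative values were radial glia -0.19, neuron -0.10, heat shock -0.59, kynurenine -0.42 and oxidative phosphorylation -0.50. With 1 library left out calls ended for IL4 receptor and JAK-STAT6 (adjusted p = 0.0614 without IL4 GFP-positive replicate 1), NF-kB (0.0935 without PBS GFP-positive replicate 1, 0.0697 without IL4 GFP-positive replicate 2) and mitochondrially encoded genes (0.09 without PBS GFP-positive replicate 2, 0.0585 without IL4 GFP-positive replicate 2, and 0.125 in fry). The kynurenine call ended without PBS GFP-negative replicate 2 (0.0709), PBS GFP-positive replicate 1 (0.0798), IL4 GFP-negative replicate 2 (0.0795) and IL4 GFP-positive replicate 1 (0.0701) or 2 (0.0596).

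Genes whose change was higher in GFP-positive cells by the same test, in log2, were COL10A1 5.21, NGFR of chromosome 12 3.34, podxl 3.06, cart4 2.65, GEM 2.57, aanat2 2.40, COL1A2 2.18, ldlra 2.09, pde4cb 2.07, HMGCS1 2.02, PDE6H 2.00, HMOX1 1.99, DDC 1.93, il4r.1 1.88, NR2E3 1.81, MCM5 1.74, flt1 1.67, stat6 1.64, kdrl 1.63, il13ra1 1.52, GCH1 1.46, DHX58 1.39, ascl1a 1.36, TIMP4 1.27, MCM2 1.27, ASMT 1.26, SOCS3 1.17, HSPA5 1.14, CCND1 1.13, TPH2 1.12, mfge8a 1.09, slc3a2a 1.09, DUSP1 1.07 and FOXJ1 1.06. Smaller differences on this side were TIMP2 0.91, PER2 0.87, SLC7A7 0.84, GNAT1 0.84, JAK1 0.80, EBF3 0.79, SPARC 0.71, mhc2dab 0.69, FABP7 of chromosome 20 0.65, mki67 0.65, ELAVL3 0.64, GAD2 0.58, PCNA 0.56, GJA1 0.54, JDP2 0.52, apoeb 0.49, NFKBIE 0.43, tubb5 0.39, lgals3bp.1 0.37, rps20 0.37, SLC1A2 0.34, cd74a 0.32, NTRK2 0.32, RPL19 0.21 and NEUROD1 0.19.

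Genes whose change was lower in GFP-positive cells by the same test were PMCH -5.28, oxt -4.24, cldna -3.29, NPY -1.78, ARR3 -1.78, cd59a -1.43, DUSP2 -1.42, krt91 -1.35, cspg5b -1.21, her8a -1.18, hsp70.1 -1.17, HTR1A -1.09 and RBFOX3 -1.01. Smaller differences on this side were atp5if1b -0.98, plp1b -0.91, hsp70l -0.91, arf4b -0.81, isg15 -0.78, SOX2 -0.73, CXCL14 -0.73, her4.2 -0.62, COX7C -0.61, ATP5MG -0.55, BHLHE41 -0.53, her4.1 -0.53, ID1 -0.52, S100B -0.48, SNAP25 -0.40 and, on chromosome 17, -0.31, STMN1 -0.34, cxcl18b -0.28, NPAS4 -0.25 and mbpa -0.24. The fitted value of PMCH rests on 2 counts in IL4 GFP-positive libraries and is no bound.

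Of these 92 genes, 76 kept the call without each library in turn and 16 lost it without at least 1, at the adjusted p given here. Among genes with positive values, NGFR of chromosome 12 lost it without PBS GFP-negative replicate 1 (0.0965), PBS GFP-positive replicate 2 (0.0700), IL4 GFP-negative replicate 2 (0.0844) or IL4 GFP-positive replicate 1 (0.387, at -3.55). The pde4cb call ended without PBS GFP-negative replicate 1 (0.0891), PBS GFP-positive replicate 1 (0.263, at 1.12), IL4 GFP-negative replicate 1 (0.0793) or 2 (0.0798) or IL4 GFP-positive replicate 1 (0.261, at 1.32), and without PBS GFP-positive replicate 2 the value was 3.97. ASMT lost it without IL4 GFP-positive replicate 1 (0.0508, at 0.79). TPH2 lost it without PBS GFP-positive replicate 2 (0.0647), IL4 GFP-negative replicate 1 (0.0613) or IL4 GFP-positive replicate 1 (0.117) or 2 (0.0671). GNAT1 kept it without PBS GFP-positive replicate 1 and IL4 GFP-negative replicate 2, and lost it without PBS GFP-negative replicate 1 (0.0656) or 2 (0.0507), PBS GFP-positive replicate 2 (0.0758), IL4 GFP-negative replicate 1 (0.0719) or IL4 GFP-positive replicate 1 (0.0725) or 2 (0.242). FABP7 of chromosome 20 lost it without IL4 GFP-negative replicate 2 (0.0696) or IL4 GFP-positive replicate 1 (0.0542). NFKBIE lost it without PBS GFP-negative replicate 1 (0.134), PBS GFP-positive replicate 1 (0.275, at 0.25), IL4 GFP-negative replicate 2 (0.151) or IL4 GFP-positive replicate 1 (0.131) or 2 (0.171). NTRK2 lost it without PBS GFP-negative replicate 2 (0.0901), PBS GFP-positive replicate 1 (0.182) or 2 (0.130), IL4 GFP-negative replicate 1 (0.215) or IL4 GFP-positive replicate 1 (0.131) or 2 (0.204). RPL19 lost it without PBS GFP-positive replicate 1 (0.0561) or 2 (0.241, at 0.10) or IL4 GFP-positive replicate 1 (0.0855) or 2 (0.294, at 0.11). Calls that ended without each of 7 libraries were those of mki67 (0.0533 to 0.159) and NEUROD1 (0.0965 to 0.423), which held without PBS GFP-negative replicate 2, and of lgals3bp.1 (0.0664 to 0.281), which held without PBS GFP-positive replicate 2. Without PBS GFP-positive replicate 1 NEUROD1 was 0.09 and lgals3bp.1 0.185, and without IL4 GFP-positive replicate 2 NEUROD1 was 0.10. Among genes with negative values, NPAS4 lost the call without PBS GFP-negative replicate 1 (0.0660) or IL4 GFP-negative replicate 1 (0.0690) or 2 (0.0731), and was -0.38 without IL4 GFP-positive replicate 1. The call of cxcl18b ended without PBS GFP-negative replicate 1 (0.0833) or IL4 GFP-negative replicate 1 (0.106), that of HTR1A without IL4 GFP-negative replicate 1 (0.0633) or IL4 GFP-positive replicate 1 (0.0542), and that of her8a without PBS GFP-negative replicate 1 (0.0717) or IL4 GFP-negative replicate 2 (0.193). Without PBS GFP-positive replicate 2 mbpa was -0.36 and SNAP25 of chromosome 17 -0.47, with the call kept.

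TPH2, the serotonin synthesis gene of the brain, fell by -2.72 ± 0.15 after IL4 in GFP-negative cells, in both libraries. A test for less pineal tissue asked whether the median of 41 pineal and photoreceptor genes lay at or below -1, since the pineal makes melatonin from serotonin, and it was -2.64 (33 fell and 1 rose), with ASMT at 170 CPM after PBS and 16.3 after IL4, GNAT1 at 169 and 17.0 and PDE6G at 144 and 22.0. Of the 41, 38 were at 1 CPM or more in PBS GFP-negative cells and 0 are in another list. Fewer serotonergic raphe neurons as the whole cause are argued against by 8 other raphe markers, whose median of -0.25 lay above the upper limit of TPH2 (-3.02 to -2.42) by 2.16, more than their SD of 0.760, while a smaller loss of these neurons or their program stays open, because 2 of the 8 fell, 3 were under 1.1 CPM and the bound set beforehand (a median above -0.5 by more than the SD) was not met. Less pineal tissue in the IL4 libraries may account for the fall, as a hypothesis found on the same data. How much tissue each sample held was not analysed here, so a regulation of TPH2 by IL4 stays open and untested.

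Microglial genes fell after IL4 in GFP-negative cells, 36 of 41, with a median of -1.39. A lower yield of all non-neural cells alike stays open. The lymphocyte median lay above that of microglia by 1.66 (permutation p = 1e-05, the smallest that 100000 permutations can give). The endothelial one lay above by 0.111 (permutation p = 0.278). Whether the first list tracks lymphocytes was not tested. The genes permuted between lists are not independent replicates, so the p-values measure no spread between libraries. Fewer microglia at an unchanged expression per cell would lower 12 core genes alike. The spread of their changes had a lower limit of 0.337, above the bound of 0.3 fixed beforehand. By that bound alone this would not be the whole cause, for these 12 genes. The margin was small. After that value was seen a condition was added, that the limit hold without any 1 gene. It did not, at 0.256 without IRF8 and 0.287 without MPEG1 (ENSDARG00000043093), a gene near the floor, so the result depends on single genes. Fewer microglia, with or without changed expression per cell, and lower expression per cell alone cannot be told apart here, with IL4 as the named difference.

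Oxidative phosphorylation genes fell after IL4 in GFP-positive cells, 92 of 103, with a median of -0.60 and a list call at the preset correlation (adjusted p = 0.0672 with an estimated correlation). The scaling between libraries is argued against as the whole cause, since the highest of 4 medians was -0.53 and the lowest -0.65. No lower share of mitochondrial RNA went with this fall, since the mitochondrially encoded genes had a median above that of the list by 0.60. Genes of chromosome M took 5.95% and 6.28% of counts in IL4 GFP-positive libraries, against 4.96% and 4.64% in PBS GFP-positive ones. The list holds nuclear genes only, so this comparison, set after the result was seen, decides no cause. A gene length or expression level trend was present: lists matched on both had a median of -0.33 (-0.41 to -0.25), so like genes fell too. Members had a median length of 880 bases, against 2315 over the tested genes. Whether such a trend accounts for the whole fall stays open. Although 0 of 10000 matched lists were as low as the list, the margin of -0.19 missed the 0.2 set beforehand. No biological explanation other than the IL4 injection is named by the design, and that one was not tested apart from this trend.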

How the results depend on the processing

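The scaling by library totals was chosen after the data were seen, all other alternatives in advance.

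The numbers of genes that passed stayed within 1.5 times under RLE and upper-quartile factors, DESeq2, voom, no filter, a stricter filter, a fit that is not robust, the 4 libraries alone and library totals, in each comparison where these ran. For IL4 in GFP-positive cells they ran from 5120 (4 libraries) to 6144 (no filter), and in GFP-negative cells from 4348 (DESeq2) to 6515 (4 libraries). The difference, which the 4 libraries cannot give, ran from 3404 (DESeq2) to 4081 (no filter). With the replicate number as a block, a pairing that the labels do not state, the counts were 5679, 4817, 3598, 14512 and 13488 in the order GFP-positive, GFP-negative, difference, sort after PBS and sort after IL4, and 14, 19, 20, 21 and 22 lists passed.

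A log2 fold change of at least 1 besides the adjusted p left 1267, 1584, 1344, 9707 and 8794 genes in that order, fewer by construction. The share of higher genes in the difference was 61.3% with TMM and 51.2% with RLE factors, and the cause was not tested. Under library totals it fell from 45.5% to 28.2% in the sort after PBS and from 48.6% to 30.6% after IL4, by the construction of that scaling, which corrects no composition.

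Camera with an estimated correlation called 4, 7, 3, 5 and 7 of 33 lists in that order, against 15, 19, 20, 21 and 22 with the preset correlation, and fry called 18, 27, 28, 32 and 29. Fry ended the camera calls of ribosomal proteins in GFP-positive cells (fry adjusted p = 0.119), oxidative phosphorylation in GFP-negative cells (0.116) and mitochondrially encoded genes in the difference (0.125). Fry reversed the direction of lists that camera did not call. These were neutrophil (fry adjusted p = 0.780), NF-kB (0.0340) and FGF (0.780) in GFP-positive cells, neurotrophins (0.870) in GFP-negative cells, Notch (0.134) in the difference, erythrocyte (0.889) and extracellular matrix (0.000638) in the sort after PBS, and IL4 receptor and JAK-STAT6 (0.00913), inflammatory (0.0569) and kynurenine (0.822) in the sort after IL4. The cause was not tested.

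Question genes changed direction under library totals: in GFP-positive cells HTR1D (0.0623) and NGFR of chromosome 3 (0.0012), and in the sort after PBS FABP7 of chromosome 20 (-0.19) and mki67 (-0.0819). NGFR of chromosome 12 did so in GFP-positive cells with voom (-0.52), and htr1aa in GFP-negative cells with upper-quartile factors (0.0174). The cause was not tested.

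With 1 library left out at a time the counts ran from 4718 to 5653 in GFP-positive cells, 3195 to 5629 in GFP-negative cells, 2509 to 3866 for the difference, 13145 to 14913 in the sort after PBS and 12003 to 14062 after IL4. The GFP-negative count was 3244 without IL4 GFP-negative replicate 1 and 3195 without replicate 2, and the difference 2509 without replicate 1. Fewer samples are part of the cause by construction. Lists passed in numbers of 13 to 16, 18 to 20, 17 to 20, 21 to 23 and 20 to 23.

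Lists that did not pass and changed direction with 1 library left out had these ranges of adjusted p. In GFP-positive cells they were neutrophil 0.570 to 0.990, mural 0.603 to 0.931, NF-kB 0.620 to 0.991, Wnt 0.473 to 0.991 and FGF 0.766 to 0.991. In GFP-negative cells they were radial glia 0.711 to 0.853, cholesterol synthesis 0.853 to 0.957 and kynurenine 0.553 to 0.947, and in the difference lymphocyte 0.465 to 0.944, Notch 0.641 to 0.966 and inflammatory 0.733 to 0.955. The cause was not tested.

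Question genes that changed direction with 1 library left out had these ranges of log2 fold change. In GFP-positive cells they were TPH1 of chromosome 25 -1.11 to 0.0058, htr1b -1.98 to 1.51, HTR1D -0.53 to 0.36 and NGFR of chromosome 12 -5.66 to 2.15. In GFP-negative cells they were GFAP -0.19 to 0.61, htr1b -0.0843 to 0.32, HTR1D -0.12 to 0.40, her4.1 -0.0521 to 0.18, S100B -0.0307 to 0.20, mki67 -0.26 to 0.0143 and htr1aa -0.23 to 0.19. In the difference they were htr1b -2.13 to 1.36, HTR1D -0.71 to 0.18, NGFR of chromosome 12 -3.55 to 4.255, htr1aa -0.42 to 0.0343 and ntrk2b -0.27 to 0.36. HTR1D ran from -0.49 to 0.26 in the sort after PBS and from -0.77 to 0.0346 after IL4. The libraries behind these are named above, and the cause was not tested.

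Of the genes that passed and were run under the alternatives in a comparison, 48 of 54 kept their call in GFP-positive cells under the alternatives that gave them a value, other than a log2 fold change of at least 1. So did 61 of 65 in GFP-negative cells, 24 of 32 in the difference, 43 of 46 in the sort after PBS and 28 of 30 after IL4. With a log2 fold change of at least 1, 29, 21, 11, 4 and 3 of these lost the call in that order, by construction. Depth limits genes of few counts: SLC6A4 and TPH1 of chromosome 7 had 3 or fewer counts in a group, and their folds there are given with counting limits.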

Other observations

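The lists in this part (pineal and photoreceptor genes, raphe markers, circadian clock genes, hypothalamic neuropeptides and core microglia genes) and the choice of the genes named were made after the data were seen, and their p-values are adjusted among these 5 lists.

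Pineal and photoreceptor genes fell in both fractions after IL4. In GFP-negative cells 33 of 41 fell and 1 rose (34 and 1 adjusted over the list alone, median -2.64, adjusted p = 5.65e-27, and adjusted p = 0.00104 with an estimated correlation), ASMT (ENSDARG00000098249), the last enzyme of melatonin synthesis, by -3.38 ± 0.11, PDE6H by -4.04 ± 0.13 and GNAT1 by -3.32 ± 0.11. In GFP-positive cells 26 of 41 fell (29 adjusted over the list alone, median -2.04, or -1.80 with members at 0 counts set to their bound, adjusted p = 3.55e-10, and 0.0076), ARR3 (ENSDARG00000056511) by -4.49 ± 0.23 and aanat2 by -3.62 ± 0.23. The difference between the fractions did not pass (adjusted p = 0.0821). In the sort after PBS 35 of the 41 were lower in GFP-positive cells and 2 higher, and after IL4 30 and 2.

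Circadian clock genes moved both ways, and the list did not pass. In GFP-positive cells 17 of 41 rose and 11 fell, PER2 by 1.75 ± 0.08 and cry3a by 1.23 ± 0.08 upward, BHLHE41 by -1.41 ± 0.06 downward (adjusted p = 0.0666). In GFP-negative cells 14 rose and 12 fell, PER2 by 0.88 ± 0.07 and cry3a by 1.31 ± 0.08 upward (adjusted p = 0.144). The hour of sampling was not analysed here.

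Hypothalamic neuropeptide genes fell in 10 of 23 cases and rose in 3 in GFP-positive cells (11 and 3 adjusted over the list alone, median -1.16, adjusted p = 0.0155, and 0.139 with an estimated correlation), NPY by -1.99 ± 0.11, while cart4 rose by 1.92 ± 0.29. In GFP-negative cells 10 fell and 2 rose, oxt by -2.19 ± 0.11 and avp by -3.17 ± 0.44, and the list did not pass (adjusted p = 0.0718).

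Core microglia genes fell in 11 of 12 cases in GFP-negative cells, c1qc, a complement gene, by -2.25 ± 0.10 and SLC7A7 by -1.92 ± 0.10 (median -1.91, adjusted p = 8.67e-16, and 0.0167 with an estimated correlation). In GFP-positive cells 8 of 12 fell, c1qc by -2.69 ± 0.18 (median -1.20, adjusted p = 0.00208, and 0.139). Raphe markers other than tph did not pass in GFP-positive (1 of 8 rose, median 0.47, or 0.25 at the bound, adjusted p = 0.2) or GFP-negative cells (2 of 8 fell, adjusted p = 0.458).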
